A study of Homo sapiens with 18 samples.

How the data were processed

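Poly-A selected RNA of 3 liver cancer cell lines, each as a non-target control and with stably expressed ALK-targeted inhibition, was sequenced on an Illumina platform in 3 biological replicates per group, per the labels' protocols. The means of inhibition, the annotation used for counting and the strandedness of the libraries are not given in the sources used here. The authors deposited 1 table of expected counts per gene for all 18 libraries, estimated with RSEM 1.2.15 from alignments with Bowtie2 2.1.0 to the hg38 genome, per the submitters' processing notes. Expected counts share reads that match more than 1 gene or transcript among them, so they need not be whole. Between 9.78% and 11.1% of the genes had such a value in a library. The values were not normalized between libraries, and totals ranged from 21725665 to 42062687. A count of 3 corresponded to 0.0713 to 0.138 CPM, depending on the library. Intervals and floors of counts cover counting error only, since reads were not tagged by molecule.

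Columns were assigned to samples by their names and groups were taken from the labels. Before averaging, replicates were compared. The spread between libraries of a group was 1.50 to 2.30 times the counting noise over 18 pairs and that between arms of a line 2.68 to 5.97 times over 27 pairs, so no library appeared to be a second deposit of another. Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr at default settings, which left 16238 of 26475. Libraries were scaled by TMM, and edgeR 4.0.16 in R 4.3.3 fitted 1 quasi-likelihood model with 6 group means to all 18 libraries. The tests were two-sided with Benjamini-Hochberg adjustment at 0.05. They covered the difference between arms in each line, its mean over the lines and, by an F test, its difference between lines. Standard errors are the absolute log2 fold change over the square root of the F statistic. Levels are means in CPM, counts scaled to a common library total, with the SD between 3 libraries.

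Gene lists were fixed before the data were examined: 32 lists with 689 entries, of which 673 were matched to the table, 34 through an older symbol, and 614 were tested. Camera from limma 3.58.1, with a preset correlation of 0.01 between genes, compared each list with the other genes, for the 30 lists with at least 3 tested members, adjusted over the lists of a line. The list of genes of the mitochondrial genome had no match in the table and the list of ALK, its ligands and its relative had LTK and MDK only, so neither was tested. MDK had edgeR adjusted p of 0.363, 0.960 and 0.218 in HepG2/C3A, SK-HEP1 and SNU-449. Camera was repeated with a correlation estimated from the data.

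Named genes were chosen by a rule fixed before the data were examined. It takes ALK, CD274, BCL2, BCL2L1 and MCL1 in every line. Per line it takes the 8 largest increases and 8 largest decreases among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the 3 libraries of each arm, which chance alone gives in some genes, and up to 4 changed members of each list described. It further takes up to 10 genes per direction changed the same way in all 3 lines and up to 8 genes changed in opposite directions with the smallest interaction p, each with at least 5 CPM in the higher group. Some of these genes are not reported here. C5, KRT17, TRIM29, LTK, MDK, the line markers and the genes listed as changed the same way with the trend removed fall outside it, and C5, KRT17 and TRIM29 were chosen after their values were seen. Positions are those of GENCODE v29 on GRCh38, 1-based.

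Alternatives planned before the data were examined were RLE scaling, library size only, no filter, a filter of at least 2 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit of each line alone, a log2 fold change of at least 1, each library left out in turn and, for lists, an estimated correlation and fry. Others were added after seeing the data. A trend of each library's deviation on GC content and log2 gene length was removed with splines of 5 degrees of freedom fitted to genes with a mean count of at least 20. GC content and length were those of the gene's longest GENCODE v29 transcript, with protein-coding transcripts preferred. Gene length means this transcript length throughout. The share of RNA of another line in each library was estimated from genes at 200 CPM or more in that line and at most 1.5% of this elsewhere, and genes for which that share could give more than 10% of the level were left out. The remaining added alternatives set libraries with a share under 0.1% apart as a term, left out genes with values that were not whole, and tested the lists with library size only, or with the trend removed and an estimated correlation.

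The edgeR tests within lines, camera, the trend removal and the estimate of another line's share were tested on simulated data. In simulations of 16149 genes with 50 genes changed per fold size, edgeR recovered 60% of 1.15-fold and 82% of 1.25-fold changes in HepG2/C3A, 68% and 92% in SK-HEP1 and 72% and 96% in SNU-449, and 100% of 1.5-fold changes in each. False calls were 8.06%, 4.26% and 5.15% of all calls. Camera called the 1 list that was shifted, in SK-HEP1 (16147 genes). Genes were drawn independently there, so this does not test the preset correlation on correlated lists. In the data the estimated correlation was 0.73 for ribosomal protein genes in HepG2/C3A. A GC trend simulated in SNU-449 gave 5226 calls before and 0 after its removal (15613 genes). The estimated share of another line's RNA erred by at most 0.0584 percentage points (16238 genes).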

Results

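RNA abundance was measured by RNA sequencing of poly-A selected RNA in 3 human liver cancer cell lines, each as a non-target control population and as a population with stably expressed ALK-targeted inhibition. ALK is a receptor tyrosine kinase. HepG2/C3A is a hepatoblastoma-derived line that keeps many hepatocyte functions, SK-HEP1 is a liver adenocarcinoma line, and SNU-449 is a hepatocellular carcinoma line with mesenchymal features. Each of the 6 groups had 3 libraries, 18 in all, described by the submitters as biological replicates. The sample titles do not say whether replicates came from separately derived populations. The p-values measure the spread between libraries and may not cover that between separately derived populations. Total counts ranged from 21725665 in replicate 3 of the SNU-449 ALK-targeted group to 42062687 in replicate 1 of the same group. The table held 26475 genes, of which 5157 had no count in any library and 16238 were tested. The labels state that HepG2 and SK-HEP1 cells grew in DMEM and SNU-449 cells in RPMI-1640, so line and medium changed together. The series title also names ABT-263, an inhibitor of BCL-2 family proteins, and treatment with an antibody against PD-1. The comparison of ALK-targeted with control cells in each line asks what changed in the RNA of cells in which ALK had been targeted.

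ALK, the targeted gene (chromosome 2, 29192774 to 29921566, minus strand, protein coding), was near the detection limit in every library. It had 0 to 6 counts per library, and 10 of the 18 libraries had none. Summed over 3 libraries, the HepG2/C3A controls held 1 ALK count and the ALK-targeted libraries 0. The SK-HEP1 controls held 4 counts and the ALK-targeted libraries 9, a ratio, scaled to library totals, of 2.01 with an exact 95% interval of 0.562 to 8.95. That ratio was 1.06 without replicate 2 of the ALK-targeted group, which held 6 of the 9 counts. The SNU-449 controls held 1 count and the ALK-targeted libraries 2, a ratio of 2.32 with an interval of 0.121 to 137. These intervals cover counting error only. ALK did not pass the expression filter, and without a filter its edgeR adjusted p was 0.676, 0.754 and 0.846 in HepG2/C3A, SK-HEP1 and SNU-449. A lower ALK level in the ALK-targeted groups was not detectable at this depth, and the group labels could not be checked against the targeted gene. LTK, the receptor most closely related to ALK, had 109 to 171 counts per library in HepG2/C3A and 0 to 8 in the other lines.

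Marker genes separated the lines. ALB, which encodes the plasma protein albumin, was at 16555 ± 471 CPM (counts scaled to a common library total, mean ± SD, n = 3) in HepG2/C3A controls, 101 ± 42.8 in SK-HEP1 controls and 27.8 ± 23.4 in SNU-449 controls. COL1A1, a chain of type I collagen, was at 1211 ± 14.3 CPM in SNU-449 controls, 10.2 ± 0.149 in SK-HEP1 controls and 1.38 ± 1.69 in HepG2/C3A controls. VIM, the intermediate filament protein of mesenchymal cells, was at 5033 ± 24.5 CPM in SK-HEP1 controls, 5458 ± 59.6 in SNU-449 controls and 31.5 ± 24.1 in HepG2/C3A controls. Of the 32 fixed hepatocyte genes tested, 29 exceeded 5 CPM in each HepG2/C3A library. The endothelial markers PECAM1 and CDH5 were at 0.0169 ± 0.0293 and 0.0295 ± 0.00398 CPM in SK-HEP1 controls, 1.69 ± 0.403 and 0.407 ± 0.0443 in HepG2/C3A controls and 0.316 ± 0.121 and 0.506 ± 0.0718 in SNU-449 controls. PRAME, a cancer-testis antigen, was at 99.8 ± 1.51 CPM in SK-HEP1 controls, 0.649 ± 0.501 in HepG2/C3A controls and 0.377 ± 0.150 in SNU-449 controls.

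Genes that were nearly exclusive to one line were also read at a low level in the other lines, at 0.015% to 1.10% of their level in the source line. This share differed between libraries of a line, as the plot of shares per library shows. In SK-HEP1 the share matching HepG2/C3A was 0.747% ± 0.293 (SD, n = 3) in controls and 0.358% ± 0.00704 in ALK-targeted libraries, and the share matching SNU-449 was 0.493% ± 0.0319 and 0.799% ± 0.261. A gene was called open to carry-over in a line when more than 10% of its level there could come from such a share in any library. This held for 2227 genes in HepG2/C3A, 2450 in SK-HEP1 and 1618 in SNU-449.

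**Figure D1:**
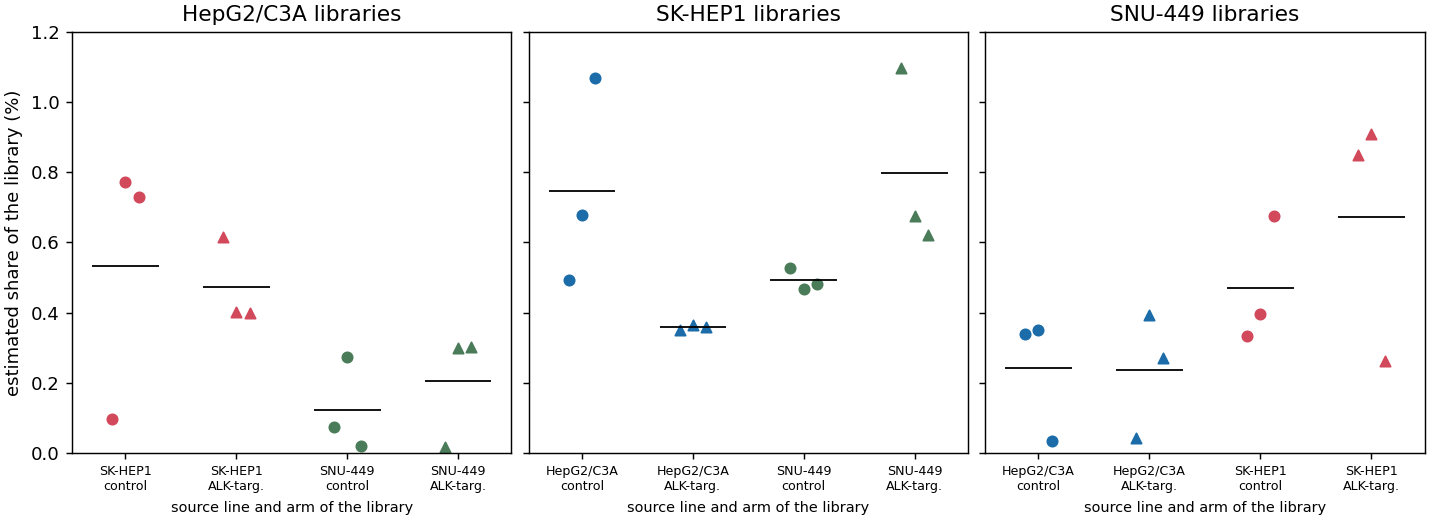
Estimated share of each library (percent, y axis) that matched RNA of another cell line, by source line and arm (x axis), with circles for control and triangles for ALK-targeted libraries and a line at the mean of 3. The SK-HEP1 panel shows HepG2/C3A shares of 0.747% on average in controls and 0.358% in ALK-targeted libraries.

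In HepG2/C3A, ALK-targeted cells had more RNA of CYP3A5, a drug-metabolising cytochrome P450, which rose from 11.4 ± 0.121 to 17.8 ± 1.03 CPM (SD, n = 3; log2 fold change 0.65, SE 0.067, edgeR adjusted p = 4.95e-07). SYNE2, which links the nuclear envelope to actin, rose from 40.01 ± 0.792 to 56.3 ± 1.39 CPM (log2 fold change 0.49, SE 0.053, edgeR adjusted p = 7.52e-07). ZBTB20, a transcriptional repressor in liver, rose with a log2 fold change of 0.53 (SE 0.070, edgeR adjusted p = 9.72e-06). ODAM, an enamel matrix-associated secreted protein, fell from 52.8 ± 1.93 to 34.0 ± 1.54 CPM (log2 fold change -0.63, SE 0.080, edgeR adjusted p = 5.17e-06). CHST15, a chondroitin sulfotransferase, and LPAR6, a receptor for lysophosphatidic acid, fell with log2 fold changes of -0.60 (SE 0.079) and -0.54 (SE 0.058; edgeR adjusted p = 9.32e-06 and 8.01e-07). The ribosomal protein genes were the group with the most changed members, and G1/S genes, endoplasmic reticulum chaperones and hypoxia and glycolysis genes were also lower by camera with a preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.327, 0.222, 0.327 and 0.311 in that order), and each held with it once a trend with GC content and gene length was removed (adjusted p = 0.0296, 4.28e-04, 0.00633 and 8.61e-05), a setting chosen after the data were seen.

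The largest changes are given among changed genes with at least 5 CPM in the higher arm and no overlap between the libraries of the arms. The other genes among the 8 largest increases by this rule were GTF2H2 (1.86, SE 0.35), CYP3A7 (0.75, SE 0.12), LRRC37A3 (0.54, SE 0.13), ZBED6 (0.51, SE 0.097) and EPPK1 (0.51, SE 0.049). The other genes among the 8 largest decreases were LY96 (-0.82, SE 0.19), the ribosomal RNA entry RNA18S5 (-0.81, SE 0.20), FSBP (-0.76, SE 0.22), SULT1E1 (-0.60, SE 0.18) and MED31 (-0.58, SE 0.10). GTF2H2, CYP3A7, LRRC37A3, EPPK1, RNA18S5 and FSBP share sequence or exons with other genes and had estimated counts that were not whole in all 6 libraries, so their values are uncertain. RNA18S5 is ribosomal RNA, and its control level varied from library to library (1111 ± 456 CPM). The calls of LY96, FSBP and SULT1E1 were lost once a trend with GC content and gene length was removed, and EPPK1 was then at 0.23. The call of RNA18S5 was lost without control replicate 1 (log2 fold change -0.42).

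Of 35 ribosomal protein genes tested, 20 fell and 1 rose (24 and 1 adjusted over the list alone; camera adjusted p = 1.53e-16, and adjusted p = 0.327 with an estimated correlation). Among them RPL7 fell from 1271 ± 43.2 to 1077 ± 16.5 CPM and RPL23 from 905 ± 34.0 to 765 ± 15.03 CPM (SD, n = 3; log2 fold change -0.24 and -0.24, edgeR adjusted p = 2.62e-06 and 2.69e-06). RPS12 and RPL6 changed by -0.19 and -0.19 on the log2 scale. Of 26 G1/S cell cycle genes, 8 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 3.00e-04, and adjusted p = 0.222 with an estimated correlation). PCNA, the sliding clamp of DNA replication, had a log2 fold change of -0.19 (SE 0.027), the replicative helicase subunits MCM3 and MCM6 had -0.11 and -0.17, and cyclin E2 (CCNE2) had -0.44 (SE 0.12). Of 27 G2/M genes, 8 fell and 3 rose, the same counts as adjusted over the list alone (camera adjusted p = 0.0270, and adjusted p = 0.698 with an estimated correlation). The mitotic kinase CDK1 fell (log2 fold change -0.28, SE 0.043), as did HMMR (-0.19) and NUSAP1 (-0.17), whereas MKI67, which encodes the proliferation antigen Ki-67, rose (0.29, SE 0.036, edgeR adjusted p = 5.36e-06). Several values were smaller by over 1.5 times with the GC and length trend removed, at -0.087 for RPL7, -0.099 for RPS12, -0.097 for RPL6, -0.094 for PCNA, -0.11 for CDK1 and 0.083 for MKI67, and HMMR and NUSAP1 lost their calls (-0.078 and -0.10).

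Of 28 hypoxia and glycolysis genes, 9 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 3.41e-04, and adjusted p = 0.311 with an estimated correlation). The glucose transporter genes SLC2A1 and SLC2A3 fell by log2 fold changes of -0.18 (SE 0.023) and -0.34 (SE 0.062), and the collagen prolyl hydroxylase subunit gene P4HA1 and the lactate dehydrogenase gene LDHA by -0.19 and -0.13. Of 17 endoplasmic reticulum chaperone genes, 5 fell and 0 rose, the same counts as adjusted over the list alone (camera adjusted p = 0.00234, and adjusted p = 0.327 with an estimated correlation), among them HSP90B1 (-0.17, SE 0.028) and DNAJB11 (-0.16, SE 0.033). Of 20 NF-kappaB target genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0270, and adjusted p = 0.222 with an estimated correlation). The pathway inhibitors TNIP1 and TNFAIP3 and the subunit gene NFKB2 rose by log2 fold changes of 0.21, 0.19 and 0.20. Of 19 FOXO target genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0270, and adjusted p = 0.327 with an estimated correlation). KLF6, the receptor gene ERBB3 and the superoxide dismutase gene SOD2 were at 0.21, 0.21 and 0.16 on the log2 scale and TXNIP, a thioredoxin inhibitor, at -0.23. The values of P4HA1, LDHA, TNFAIP3, NFKB2 and ERBB3 were -0.11, -0.081, 0.11, 0.10 and 0.083 with the GC and length trend removed, and SOD2 lost its call (0.012). The FOXO call was lost with RLE scaling (camera adjusted p = 0.0581), with library size as the only scaling (0.0534), with the GC and length trend removed (0.0961) and without control replicate 1 (0.0727). It passed with the trend removed and genes open to carry-over left out, with 16 members (camera adjusted p = 0.0361, and adjusted p = 0.313 with an estimated correlation). The G2/M call was lost with the trend removed (camera adjusted p = 0.388) and without ALK-targeted replicate 1 (0.0501), and the NF-kappaB call without control replicate 1 (0.0540). In a fit of this line alone these 3 lists had camera adjusted p of 0.0749, 0.0918 and 0.0918. FOXO and NF-kappaB targets had 0.0572 and 0.0572 with a filter of at least 2 CPM in 3 libraries and 0.0523 and 0.0653 with libraries of a low carry-over share set apart.

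In all, 2985 of the 16238 genes changed in HepG2/C3A, 1813 higher and 1172 lower (edgeR adjusted p under 0.05). Most changes were small, with a median absolute log2 fold change of 0.17 among the changed genes, and 39 changed by at least 2-fold. The changes followed GC content and gene length across genes (Spearman rho 0.31 and 0.37 over 11442 genes, which are not independent replicates), and with this trend removed 1390 genes changed, 508 higher and 882 lower. By library, the rho of GC content with the deviation from the mean of the line was -0.28 to -0.15 in controls and 0.17 to 0.31 in ALK-targeted libraries. Library preparation batches are not given in the sources used here, so for this trend batch and arm cannot be told apart.

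In SK-HEP1, the chemokine gene CXCL8 (chromosome 4, 73740506 to 73743716, plus strand) had the largest increase of the named genes, from 7.68 ± 0.319 to 22.4 ± 0.979 CPM (SD, n = 3; log2 fold change 1.55, SE 0.064, edgeR adjusted p = 1.35e-13). The cytokine gene IL24 rose from 3.78 ± 0.335 to 7.83 ± 0.479 CPM (log2 fold change 1.04, SE 0.14, edgeR adjusted p = 4.45e-05). SERPINB2, an inhibitor of plasminogen activators, rose from 271 ± 5.54 to 424 ± 4.79 CPM (log2 fold change 0.65, SE 0.062, edgeR adjusted p = 3.73e-07). CXCL1, another neutrophil-attracting chemokine, and the immediate early transcription factor EGR1 rose by 0.59 (SE 0.056) and 0.80 (SE 0.11) on the log2 scale. The lists of NF-kappaB targets, cytokines and immediate early genes were higher by camera, with 10 of 20, 6 of 24 and 7 of 16 members risen, and those of fatty acid synthesis and G1/S genes lower. CXCL8, CXCL1 and CXCL2 stand in both the NF-kappaB and the cytokine list.

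By the same rule, the other genes among the 8 largest increases were KRT34 (0.55, SE 0.074), IGFN1 (0.72, SE 0.21) and the matrix proteoglycan gene BGN (0.63, SE 0.17), of which IGFN1 and BGN were open to carry-over from SNU-449. The 8 largest decreases by that rule were all in genes of proteins secreted by hepatocytes: FGA (-1.33, SE 0.21), AGT (-1.08, SE 0.29), AMBP (-1.07, SE 0.19), C3 (-1.04, SE 0.23), SEPP1 (-1.04, SE 0.18), SERPINF1 (-1.04, SE 0.28), APOH (-1.04, SE 0.24) and SERPINA3 (-0.92, SE 0.15). FGA, a fibrinogen chain, went from 5.07 ± 2.14 to 1.94 ± 0.360 CPM (SD, n = 3). Without control replicate 3 the calls of SERPINF1 and APOH were lost (-0.63 and -0.67), and without ALK-targeted replicate 1 that of IGFN1 (0.43). All 8 were open to carry-over from HepG2/C3A, whose share in these libraries was 0.747% ± 0.293 in controls and 0.358% ± 0.00704 in ALK-targeted libraries. Of 32 hepatocyte genes, 7 fell and 0 rose (19 and 0 adjusted over the list alone; camera adjusted p = 7.40e-12, and adjusted p = 0.135 with an estimated correlation), and 30 of the 32 were open to carry-over.

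Of 20 NF-kappaB target genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 7.96e-31). Besides CXCL8 and CXCL1 these included the adhesion molecule gene ICAM1, from 82.7 ± 2.44 to 105 ± 1.90 CPM (SD, n = 3; log2 fold change 0.34), and IER3 (0.32, SE 0.029). Of 24 cytokine and chemokine genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 4.10e-11). The interleukin-1 gene IL1B rose from 60.2 ± 0.498 to 85.7 ± 1.46 CPM (SD, n = 3; log2 fold change 0.51) and CXCL2 by 0.88 (SE 0.14). Of 16 immediate early stress genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 4.01e-19). The heat shock genes HSPA1A and HSPA1B, near-identical copies whose reads cannot be fully told apart, had log2 fold changes of 0.40 and 0.36, and the phosphatase gene DUSP1 had 0.23 (SE 0.034). Of 20 ERK pathway output genes, 4 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 1.82e-07), namely IER3, EGR1, PHLDA1 (0.13) and the ERK phosphatase gene DUSP6 (0.18, SE 0.047). EGR1 and IER3 also stand in other lists, so the lists are not independent.

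Of 17 fatty acid synthesis genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 1.55e-09). The stearoyl-CoA desaturase gene SCD fell from 188 ± 2.13 to 145 ± 4.37 CPM (SD, n = 3; log2 fold change -0.38). SREBF1, the transcription factor of this pathway, the acetyl-CoA carboxylase gene ACACA and the fatty acid synthase gene FASN fell by log2 fold changes of -0.31, -0.26 and -0.22. SCD was open to carry-over in this line. Of 26 G1/S genes, 7 fell and 0 rose (12 and 0 adjusted over the list alone; camera adjusted p = 3.11e-06), among them MCM2 (-0.14, SE 0.025), MCM3 (-0.10) and MCM6 (-0.10). Of 17 endoplasmic reticulum chaperone genes, 5 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 2.38e-10), including HSPA5, the main chaperone of that compartment (0.15, SE 0.024), and MANF (0.23, SE 0.031). Of 28 hypoxia and glycolysis genes, 9 rose and 0 fell (12 and 1 adjusted over the list alone; camera adjusted p = 3.88e-07), among them NDRG1 (0.36, SE 0.058), BNIP3L (0.18) and P4HA2 (0.18). The calls of these 8 lists, from NF-kappaB targets to hypoxia and glycolysis genes, held with an estimated correlation. The adjusted p was then 6.26e-07 for NF-kappaB targets, 0.00352 for cytokines, 0.00181 for immediate early genes and 0.0228 for ERK output. It was 0.00193 for fatty acid synthesis, 0.0286 for G1/S, 0.0194 for chaperones and 0.0304 for hypoxia.

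A further 10 lists passed with the preset correlation and not with an estimated one. NRF2 targets (3 of 22 rose and 3 fell; camera adjusted p = 0.00713, and adjusted p = 0.374 with an estimated correlation) included the haem oxygenase gene HMOX1 at 0.36 (SE 0.029) and the thioredoxin reductase gene TXNRD1 at 0.20, against ABCC2 at -0.21, which was open to carry-over. Mesenchymal and matrix genes (4 of 31 rose; camera adjusted p = 0.0117, and adjusted p = 0.444 with an estimated correlation) included the collagen cross-linking enzyme gene LOX at 0.41 (SE 0.036) and MMP14 at 0.27, while the list's median was -0.012 and its camera direction up. G2/M genes (6 of 27 fell and 1 rose; camera adjusted p = 5.58e-05, and adjusted p = 0.135 with an estimated correlation) included CENPF at -0.21 and MKI67 at -0.17. Epithelial genes (5 of 20 fell and 1 rose; camera adjusted p = 2.49e-04, and adjusted p = 0.128 with an estimated correlation) included the keratin genes KRT18 at -0.15 and KRT8 at -0.11 and the tight junction gene CLDN1 at 0.30. Of the 20 epithelial genes, 11 were open to carry-over, and without these the call was lost (camera adjusted p = 0.396). FOXO targets (3 of 19 rose; camera adjusted p = 0.00884, and adjusted p = 0.135 with an estimated correlation) included KLF6 at 0.27 and GADD45A at 0.29. STAT3 targets (4 of 17 fell and 1 rose; camera adjusted p = 0.00316, and adjusted p = 0.135 with an estimated correlation) included STAT3 at -0.094, and their fallen members FGA and FGG were among 10 members open to carry-over, without which the call was lost (camera adjusted p = 0.484). Interferon-stimulated genes (2 of 31 fell; camera adjusted p = 0.0300, and adjusted p = 0.135 with an estimated correlation) included MX1 at -0.58 (SE 0.15), with a median of -0.056 and a mean of 0.087. MHC class I genes (4 of 19 rose; camera adjusted p = 0.0477, and adjusted p = 0.374 with an estimated correlation) included B2M at 0.11 and HLA-B at 0.12. Anti-apoptotic BCL-2 family genes (1 of 5 rose; camera adjusted p = 0.0382, and adjusted p = 0.128 with an estimated correlation) had BCL2A1 as the risen member, from 0.631 ± 0.152 to 1.76 ± 0.222 CPM (SD, n = 3; log2 fold change 1.48, SE 0.26). Ribosomal protein genes (1 of 35 rose; camera adjusted p = 0.0258, and adjusted p = 0.613 with an estimated correlation) had RPL7 as the risen member at 0.11, with a median of 0.022. The calls of B2M and RPL7 were lost with the GC and length trend removed (0.048 and 0.051). With library size as the only scaling the camera adjusted p was 0.0526 for MHC class I genes and 0.0740 for ribosomal protein genes, and the median of FOXO targets was -0.0016 in place of 0.0086.

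Several of these 10 calls were lost when 1 library was left out. Without control replicate 1 the camera adjusted p was 0.385 for NRF2 targets, 0.111 for interferon-stimulated genes and 0.0651 for anti-apoptotic BCL-2 family genes. Without control replicate 3 it was 0.0738 for anti-apoptotic and 0.153 for MHC class I genes. Without ALK-targeted replicate 1 it was 0.105 for NRF2 targets, 0.0537 for interferon-stimulated, 0.114 for MHC class I and 0.0565 for mesenchymal and matrix genes. Without ALK-targeted replicate 2 it was 0.0620 for anti-apoptotic and 0.0519 for ribosomal protein genes. In a fit of this line alone STAT3 targets, anti-apoptotic and MHC class I genes had 0.111, 0.0794 and 0.0572, and with a filter of at least 2 CPM in 3 libraries the last 2 of these lists had 0.492 and 0.0610. The ribosomal call was lost with the GC and length trend removed (camera adjusted p = 0.773), and in that setting the G2/M, epithelial and FOXO lists passed with an estimated correlation as well (adjusted p = 2.90e-04, 0.0332 and 0.0440).

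In all, 878 genes changed in SK-HEP1, 452 higher and 426 lower, with a median absolute log2 fold change of 0.17 among them and 60 at 2-fold or more (edgeR adjusted p under 0.05). Of those 60, 9 were higher and 51 lower. With genes open to carry-over left out, 436 of all changed genes were higher and 329 lower. With library size as the only scaling the split was 435 higher and 633 lower, and without control replicate 1 it was 305 higher and 353 lower. The count was 1372 with DESeq2 and 1551 in a fit of this line alone, and it lay between 446 (without control replicate 2) and 658 (without control replicate 1) when 1 library was left out. The changes had a Spearman rho of -0.16 with GC content and -0.16 with gene length over 11442 genes, which are not independent replicates. With this trend removed 1127 genes changed, 592 higher and 535 lower. By library, the rho of GC content was 0.42 in control replicate 2 and -0.078 and -0.10 in control replicates 1 and 3. In ALK-targeted libraries it was -0.25 to 0.082.

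In SNU-449, FASN, the fatty acid synthase gene (chromosome 17, 82078333 to 82098332, minus strand), fell from 1238 ± 28.2 to 876 ± 31.6 CPM (SD, n = 3; log2 fold change -0.50, SE 0.030, edgeR adjusted p = 4.05e-10), with a log2 fold change of -0.30 once the GC and length trend was removed. WNT2, which encodes a secreted Wnt ligand, fell from 27.0 ± 0.581 to 18.9 ± 0.914 CPM (log2 fold change -0.51, SE 0.086, edgeR adjusted p = 1.23e-04). KIF26B, a kinesin family gene, fell from 8.19 ± 0.155 to 5.42 ± 0.349 CPM (log2 fold change -0.59, SE 0.11, edgeR adjusted p = 3.78e-04). STK38L, a kinase of the NDR family, rose from 32.8 ± 2.26 to 47.0 ± 1.52 CPM (log2 fold change 0.52, SE 0.048, edgeR adjusted p = 1.39e-07). AREG, a ligand of the EGF receptor, and the cadherin gene CDH6 rose by 0.52 (SE 0.14) and 0.53 (SE 0.13) on the log2 scale. Fatty acid and cholesterol synthesis genes were lower as lists by camera, with a preset and with an estimated correlation. G1/S genes and YAP/TEAD targets were lower with the preset correlation only (adjusted p = 0.0621 and 0.10 with an estimated correlation).

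By the same rule, the other genes among the 8 largest increases were RGPD5 (0.75, SE 0.22), FSBP (0.65, SE 0.21), HMGN5 (0.55, SE 0.11), the read-through entry ARMCX5-GPRASP2 (0.51, SE 0.13) and SLC16A4 (0.51, SE 0.14). The other genes among the 8 largest decreases were the read-through entry MINOS1-NBL1 (-2.12, SE 0.41), TRIM67 (-0.49, SE 0.081), CLDN11 (-0.48, SE 0.086), the signal recognition particle RNA entry RN7SL2 (-0.46, SE 0.074) and IGFN1 (-0.46, SE 0.058). RGPD5, FSBP, ARMCX5-GPRASP2, MINOS1-NBL1 and RN7SL2 share reads with other entries and are uncertain. The calls of FSBP, HMGN5, ARMCX5-GPRASP2 and SLC16A4 were lost with the GC and length trend removed, and TRIM67 and IGFN1 were then at -0.32 and -0.25.

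Of 17 fatty acid synthesis genes, 11 fell and 0 rose, the same counts as adjusted over the list alone (camera adjusted p = 7.04e-10, and adjusted p = 0.00212 with an estimated correlation). Besides FASN these included ACACA, from 259 ± 7.30 to 207 ± 9.12 CPM (SD, n = 3; log2 fold change -0.32), SREBF1 (-0.20, SE 0.028) and SCD (-0.17, SE 0.025). Of 25 cholesterol synthesis genes, 14 fell and 1 rose (15 and 2 adjusted over the list alone; camera adjusted p = 7.50e-07, and adjusted p = 0.0367 with an estimated correlation). The reductase gene DHCR7, which acts in the last step of the pathway, had a log2 fold change of -0.19 (SE 0.026) and the squalene synthase gene FDFT1 -0.13. Of 26 G1/S genes, 11 fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 5.01e-05, and adjusted p = 0.0621 with an estimated correlation), including MCM2 (-0.20, SE 0.025), the licensing factor gene CDT1 (-0.25, SE 0.032) and the transcription factor gene E2F1 (-0.23, SE 0.040). Once the GC and length trend was removed, ACACA was at -0.19, DHCR7 at -0.11, MCM2 at -0.094, CDT1 at -0.14 and E2F1 at -0.15, and SREBF1 lost its call (-0.066).

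Of 20 YAP/TEAD target genes, 12 fell and 2 rose, the same counts as adjusted over the list alone (camera adjusted p = 1.02e-04, and adjusted p = 0.10 with an estimated correlation). Among them were AMOTL2 (-0.33, SE 0.026) and WWC1 (-0.26, SE 0.032), which encode negative regulators of YAP. Of 20 ERK output genes, 7 fell and 2 rose, the same counts as adjusted over the list alone (camera adjusted p = 0.00973, and adjusted p = 0.311 with an estimated correlation). The cyclin D1 gene CCND1 fell from 369 ± 7.51 to 295 ± 8.13 CPM (SD, n = 3; log2 fold change -0.32), and FOSL1, a subunit of the AP-1 transcription factor, and the ERK phosphatase gene DUSP4 by log2 fold changes of -0.29 and -0.17. Of 20 NF-kappaB targets, 8 fell and 2 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.0122, and adjusted p = 0.0621 with an estimated correlation), with NFKB2 at -0.22, ICAM1 at -0.15, RELB at -0.26 and IER3 at 0.12. Of 35 ribosomal protein genes, 15 rose and 1 fell (16 and 2 adjusted over the list alone; camera adjusted p = 1.22e-05, and adjusted p = 0.965 with an estimated correlation), with RPL7 at 0.27 (SE 0.028) and RPL23 at 0.22 (SE 0.029). The ERK call was lost with the GC and length trend removed (camera adjusted p = 0.0930), and the NF-kappaB call without ALK-targeted replicate 1 (0.0759) and in a fit of this line alone (0.0531). With the trend removed G1/S genes also passed with an estimated correlation (adjusted p = 0.00200), AMOTL2, WWC1, NFKB2 and RPL7 were at -0.21, -0.12, -0.11 and 0.11, and DUSP4 and ICAM1 lost their calls (-0.075 and -0.059).

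In all, 3455 genes changed in SNU-449, 1479 higher and 1976 lower, with a median absolute log2 fold change of 0.17 among them and 45 at 2-fold or more (edgeR adjusted p under 0.05). The changes followed GC content across genes (Spearman rho -0.48 over 11442 genes, which are not independent replicates) and gene length (-0.19), and with this trend removed 1742 genes changed, 928 higher and 814 lower. With library size as the only scaling the split was 1835 higher and 1734 lower. By library, the rho of GC content was 0.31 to 0.41 in controls and -0.54 to -0.22 in ALK-targeted libraries, and here too preparation batch and arm cannot be told apart.

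CD274, BCL2, BCL2L1 and MCL1 relate to the drug and the antibody in the series title. CD274, which encodes the PD-1 ligand PD-L1, was at 0.0742 ± 0.0273 CPM in HepG2/C3A controls, 0.505 ± 0.179 in SK-HEP1 controls and 2.69 ± 0.259 in SNU-449 controls (SD, n = 3). Its log2 fold change was 0.56 (SE 0.68), 0.41 (SE 0.28) and -0.047 (SE 0.18), with edgeR adjusted p of 0.675, 0.450 and 0.922. In HepG2/C3A it had at most 6 counts per library. BCL2 had log2 fold changes of 0.19, -0.068 and -0.18 (SE 0.098, 0.11 and 0.083; edgeR adjusted p = 0.208, 0.803 and 0.143). BCL2L1, which encodes BCL-xL, fell in SNU-449 from 267 ± 2.54 to 232 ± 9.74 CPM (SD, n = 3; log2 fold change -0.20, SE 0.028, edgeR adjusted p = 1.60e-05), and its log2 fold change there was -0.13 with the GC and length trend removed. Its values in HepG2/C3A and SK-HEP1 were 0.049 (SE 0.027) and 0.0077 (SE 0.029; edgeR adjusted p = 0.243 and 0.933). MCL1 rose in SNU-449 (log2 fold change 0.071, SE 0.022, edgeR adjusted p = 0.0209) and had values of 0.018 (SE 0.022) and 0.055 (SE 0.022) in HepG2/C3A and SK-HEP1 (edgeR adjusted p = 0.67 and 0.157).

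Lists that passed in no line are given with camera adjusted p in HepG2/C3A, SK-HEP1 and SNU-449. Pro-apoptotic BCL-2 family genes had 0.578, 0.165 and 0.906, p53 targets 0.450, 0.229 and 0.798, immune checkpoint ligands 0.874, 0.377 and 0.970, and ATF4 and amino acid stress genes 0.294, 0.794 and 0.458. Wnt/beta-catenin targets had 0.874, 0.200 and 0.999, and replication-dependent histone genes, few of whose transcripts are polyadenylated, had 0.568, 0.585 and 0.458. Markers of other cell types had 0.615, 0.231 and 0.906 for endothelial genes, 0.444, 0.420 and 0.510 for fibroblast and stellate cell genes and 0.834, 0.557 and 0.970 for leukocyte genes. ATF4 and amino acid stress genes passed as lower in HepG2/C3A with the GC and length trend removed (camera adjusted p = 2.68e-06, and adjusted p = 0.0276 with an estimated correlation). With genes open to carry-over left out, Wnt/beta-catenin targets and immune checkpoint ligands passed as higher in SK-HEP1 with the preset correlation (camera adjusted p = 0.0410 and 0.0468). These lists then had 7 and 11 members, and with the GC and length trend also removed they had adjusted p = 0.0433 and 0.0870 with an estimated correlation. With all 19 and 15 tested members and the trend kept, it was 0.483 and 0.601 with an estimated correlation, and the direction of Wnt/beta-catenin targets was down. Hepatocyte genes had camera adjusted p of 0.436 in HepG2/C3A and 0.889 in SNU-449.

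**Figure D2:**
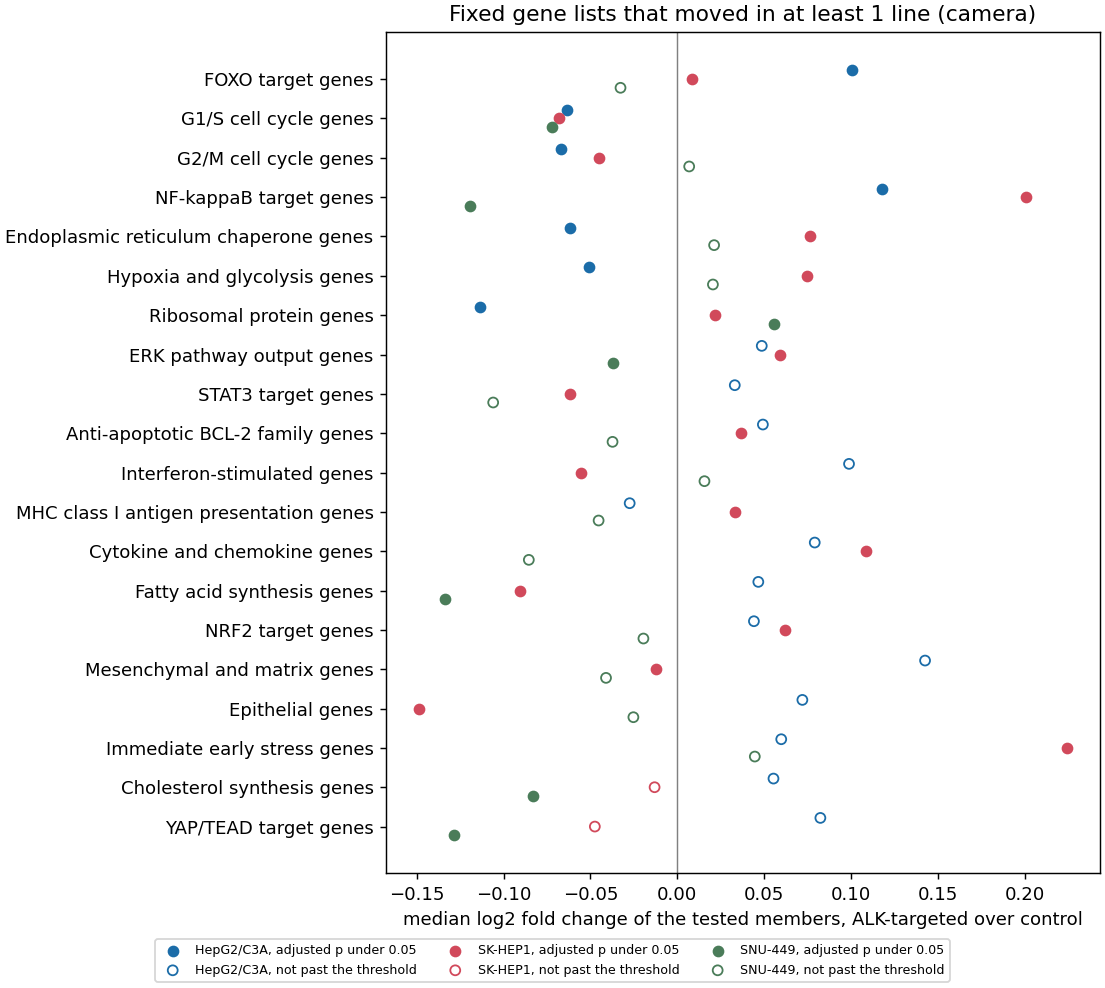
Median log2 fold change of the tested members of each fixed list (x axis, ALK-targeted over control) for 20 of the lists that passed camera in at least 1 line (y axis), with 1 point per line, filled where the adjusted p was under 0.05. G1/S genes lie below 0 in all 3 lines, at -0.063, -0.068 and -0.072, and ribosomal protein genes at -0.11 in HepG2/C3A and 0.055 in SNU-449. Hepatocyte genes in SK-HEP1, with a median of -0.97, are left out for scale.

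Averaged over the 3 lines, EGR1 rose with a mean log2 fold change of 0.52 (edgeR adjusted p = 5.07e-06), TUBA1A, an alpha-tubulin gene, with 0.21 (2.64e-07) and KLF6, a zinc finger transcription factor, with 0.18 (1.66e-08). ID3 and ID1, which encode inhibitors of DNA binding by helix-loop-helix factors, fell by averages of -0.19 (1.21e-04) and -0.17 (1.71e-04), and both were open to carry-over in at least 1 line. On this average 563 genes changed, 314 higher and 249 lower, and 6 of them changed by at least 2-fold. The count was 1078 with DESeq2, and it was 362 without replicate 2 of the HepG2/C3A ALK-targeted group and 363 without replicate 2 of the SNU-449 controls. The balance turned to 392 higher and 450 lower with the GC and length trend removed and to 264 higher and 367 lower without replicate 1 of the HepG2/C3A controls. It was 236 higher and 242 lower without replicate 1 of the SK-HEP1 controls and 234 higher and 249 lower without replicate 1 of the SNU-449 ALK-targeted group.

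Of the genes that changed in opposite directions between lines, those with the smallest interaction p are given here. HIPK2, a nuclear kinase (chromosome 7, 139561570 to 139777778, minus strand), had log2 fold changes of 0.39 in HepG2/C3A, 0.12 in SK-HEP1 and -0.37 in SNU-449 (SE 0.030, 0.031 and 0.029; interaction edgeR adjusted p = 2.57e-10). FASN changed by 0.25 in HepG2/C3A, -0.22 in SK-HEP1 and -0.50 in SNU-449 (SE 0.030, 0.030 and 0.030; interaction edgeR adjusted p = 2.90e-10). SPEN, a transcriptional corepressor, changed by 0.32 in HepG2/C3A, -0.17 in SK-HEP1 and -0.36 in SNU-449 (SE 0.029, 0.028 and 0.031; interaction edgeR adjusted p = 4.18e-10). SNRPE, a core protein of spliceosomal ribonucleoproteins, changed by -0.41 in HepG2/C3A, 0.12 in SK-HEP1 and 0.32 in SNU-449 (SE 0.036, 0.030 and 0.029; interaction edgeR adjusted p = 6.64e-10). MACF1, a microtubule and actin cross-linker, and SRCAP, a chromatin remodelling ATPase, were higher in HepG2/C3A and lower in SK-HEP1 and SNU-449, with 0.32, -0.11 and -0.33 for MACF1 and 0.34, -0.12 and -0.26 for SRCAP (interaction edgeR adjusted p = 4.55e-10 for each). MYO18A, an unconventional myosin, and PLEC, a cytoskeletal linker, rose in HepG2/C3A (0.31 and 0.42) and fell in SNU-449 (-0.33 and -0.32), while their SK-HEP1 values of -0.088 and -0.012 did not pass (edgeR adjusted p = 0.0564 and 0.888; interaction edgeR adjusted p = 4.55e-10 and 6.64e-10). Removal of the GC and length trend made most of these values smaller by over 1.5 times. In HepG2/C3A and SNU-449 they were then 0.17 and -0.21 for HIPK2, 0.097 and -0.19 for SPEN, -0.21 and 0.12 for SNRPE, 0.13 and -0.20 for MACF1, 0.086 and -0.14 for MYO18A and 0.13 and -0.078 for PLEC. FASN was at 0.035 in HepG2/C3A (edgeR adjusted p = 0.227) and -0.30 in SNU-449, and SRCAP at 0.090 in HepG2/C3A. In SK-HEP1, SPEN was at -0.11 and MACF1 at -0.062, and the calls of SRCAP in SK-HEP1 and SNU-449 and of SNRPE in SK-HEP1 were lost.

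Some lists that passed in opposite directions also passed a test of the difference itself. NF-kappaB targets were higher in SK-HEP1 than in SNU-449 by this measure (camera adjusted p = 2.06e-29, and adjusted p = 8.18e-07 with an estimated correlation), and ERK output genes likewise (camera adjusted p = 1.38e-11, and adjusted p = 0.00692 with an estimated correlation). Endoplasmic reticulum chaperones (camera adjusted p = 2.04e-09, and adjusted p = 0.0561 with an estimated correlation) and hypoxia and glycolysis genes (camera adjusted p = 6.48e-07, and adjusted p = 0.0561 with an estimated correlation) changed differently in HepG2/C3A and SK-HEP1. Ribosomal protein genes differed between HepG2/C3A and SNU-449 (camera adjusted p = 2.67e-13, and adjusted p = 0.611 with an estimated correlation) and between HepG2/C3A and SK-HEP1 (camera adjusted p = 5.94e-14, and adjusted p = 0.406 with an estimated correlation). NF-kappaB targets differed between HepG2/C3A and SNU-449 (camera adjusted p = 0.0113, and adjusted p = 0.0803 with an estimated correlation).

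In all, the change differed between lines for 4573 of the 16238 genes (edgeR interaction test, adjusted p under 0.05), and 1708 genes changed in opposite directions in a pair of lines. In HepG2/C3A and SNU-449, 1602 genes changed in opposite directions, where independent lists of these sizes would share 327, and 43 changed the same way. Across 11577 genes, which are not independent replicates, Spearman's rho of the log2 fold changes was -0.50 between these lines (Pearson's r -0.22). SK-HEP1 and SNU-449 shared 189 genes that rose, against 41.2 of independent lists, and 170 that fell, against 51.8, with a rho of 0.31 (r 0.14). HepG2/C3A and SK-HEP1 had a rho of -0.20 (r 0.032). The changes in SK-HEP1 and SNU-449 followed GC content (rho -0.16 and -0.48) and gene length (-0.16 and -0.19) with the same sign. The overlap of SK-HEP1 and SNU-449 was not tested with the trend removed, so the part that this trend may give is not known. With the GC and length trend removed, 2502 genes differed between lines, and 446 changed in opposite directions in HepG2/C3A and SNU-449 where independent lists would share 78.5, with a rho of -0.25.

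A small set of genes changed the same way in all 3 lines. EGR1 (chromosome 5, 138465490 to 138469315, plus strand) had log2 fold changes of 0.33 in HepG2/C3A, 0.80 in SK-HEP1 and 0.41 in SNU-449 (SE 0.067, 0.11 and 0.099; edgeR adjusted p = 8.84e-04, 8.72e-05 and 0.00405), and its change differed between lines (interaction edgeR adjusted p = 0.0280). TUBA1A rose by 0.17, 0.25 and 0.22, the AP-1 subunit genes JUN by 0.17, 0.13 and 0.073 and JUND by 0.21, 0.16 and 0.15, KLF6 by 0.21, 0.27 and 0.068, and the lysosomal membrane protein gene SCARB2 by 0.080, 0.14 and 0.077. The helicase subunit genes MCM6 (-0.17, -0.10 and -0.089) and MCM7 (-0.092, -0.084 and -0.13), the cyclin A2 gene CCNA2 (-0.12, -0.10 and -0.099), ID1 (-0.16, -0.22 and -0.13) and ID3 (-0.10, -0.30 and -0.17) fell in each line. The remaining gene of the 12, the complement gene C5, was below 5 CPM in SK-HEP1 and is named after its values were seen. Its log2 fold changes were -0.11, -0.45 and -0.16.

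These 6 genes higher and 6 lower in every line compare with 4.60 and 3.74 that independent lists of these sizes would share. With the GC and length trend removed 24 genes changed the same way, 14 higher and 10 lower, against 1.13 and 1.56 of independent lists, and the calls of ID3 and CCNA2 in HepG2/C3A and of MCM7 in SNU-449 were lost. JUN was then at 0.083 in HepG2/C3A and 0.17 in SNU-449, MCM7 at -0.16 in HepG2/C3A and CCNA2 at -0.17 in SNU-449. The count was 19 with DESeq2, and it was 6 without replicate 2 of the SK-HEP1 ALK-targeted group or without replicate 3 of the SNU-449 controls. It was 7 without replicate 3 of the SK-HEP1 controls, replicate 3 of the SK-HEP1 ALK-targeted group, replicate 1 of the SNU-449 controls or replicate 1 of the SNU-449 ALK-targeted group. G1/S genes were the only list of the 30 tested that passed camera in the same direction in all 3 lines, and that call held with an estimated correlation only in SK-HEP1. It held with an estimated correlation in each line once the GC and length trend was removed (adjusted p = 4.28e-04, 7.01e-04 and 0.00200).

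**Figure D3:**
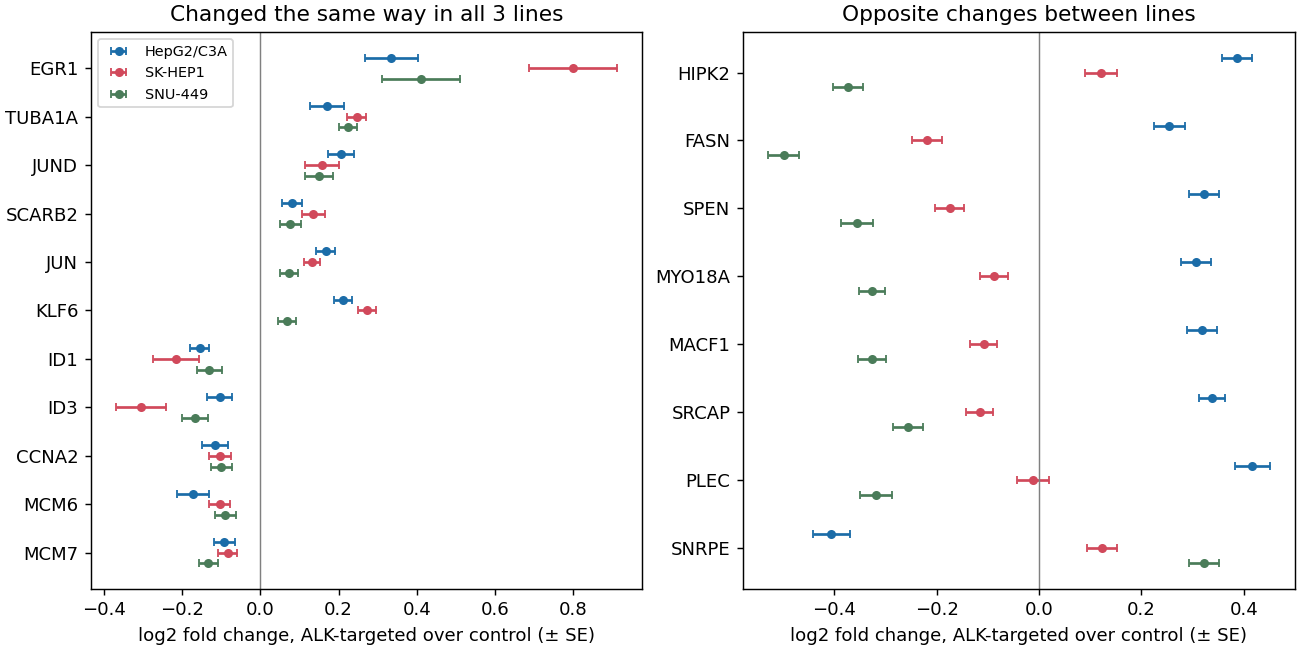
Log2 fold change of ALK-targeted over control cells with its standard error (x axis) in HepG2/C3A, SK-HEP1 and SNU-449 for 11 of the 12 genes changed the same way in all 3 lines (left; C5 fell below the level set for naming) and 8 genes with opposite changes between lines (right). EGR1 had 0.33, 0.80 and 0.41, and HIPK2 lies on opposite sides of 0 in HepG2/C3A (0.39) and SNU-449 (-0.37).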

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

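The splits of the samples in this part were planned. The tests of GC content, of carry-over, of the cells' own expression and of handling were chosen after the results were seen. The change on ALK targeting differed between lines for 4573 genes by the edgeR interaction test, and this set the genes and lists that follow apart. HIPK2 had an interaction adjusted p of 2.57e-10, FASN 2.90e-10, SPEN 4.18e-10, MYO18A, MACF1 and SRCAP 4.55e-10 each, and PLEC and SNRPE 6.64e-10 each. Of the 16238 genes tested 4573 passed, and of the 255 named genes, chosen in part by this test and by large changes, 203. By camera on the difference, endoplasmic reticulum chaperones (adjusted p = 2.04e-09), hypoxia and glycolysis genes (6.48e-07) and ribosomal protein genes (5.94e-14) differed between HepG2/C3A and SK-HEP1. NF-kappaB targets (0.0113) and ribosomal protein genes (2.67e-13) differed between HepG2/C3A and SNU-449, and ERK output genes (1.38e-11) and NF-kappaB targets (2.06e-29) between SK-HEP1 and SNU-449. Of the comparisons in this paragraph up to here, only the last, of SK-HEP1 with SNU-449, passed with an estimated correlation (adjusted p = 0.00692 and 8.18e-07). Fatty acid synthesis genes were not among them, since in HepG2/C3A 6 of 17 rose and 1 fell with a camera adjusted p of 0.0501. Their difference passed between HepG2/C3A and SK-HEP1 (camera adjusted p = 2.05e-06, and adjusted p = 0.0304 with an estimated correlation). It also passed between HepG2/C3A and SNU-449 (camera adjusted p = 2.53e-05, and adjusted p = 0.0368 with an estimated correlation).

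In HepG2/C3A and SNU-449, 1602 genes changed in opposite directions. The changes followed GC content with opposite signs in these lines, and removing the trend with GC content and gene length lowered the number to 446, so the trend may account for a large part of it. The 446 were still 5.68 times the number of independent lists (5.79 to 7.07 with 1 library left out), against 4.89 times before removal. The ratio did not fall with the trend, and a part of the trend left in by the splines could give the same result. This ratio therefore cannot decide whether the trend was the whole cause. Among genes not open to carry-over in either line the ratio was 4.40 (4.58 to 5.00 with 1 library left out). Such genes could still draw up to 10% of their level from carry-over. The median absolute log2 fold change of the changed genes was 0.17 in each of these lines, so many changes were small. This ratio therefore cannot decide on RNA carried over between lines for changes within 10%. A difference between the lines in their response to ALK targeting stays open, and so do their medium, which the design confounds with line, and library preparation batches, which are not given in the sources used here and cannot be told apart from arm.

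Hepatocyte genes were lower in SK-HEP1 libraries with ALK targeting by camera with the preset correlation (adjusted p = 7.40e-12), and not with an estimated one (adjusted p = 0.135). For 16 members not used to estimate the share of HepG2/C3A RNA, the observed log2 change lay a median of -0.019 from that which the share predicts (interquartile range -0.15 to 0.64), as carry-over needs, with medians of -0.73 observed and -1.03 predicted. Their control level was 1.0 times that which the share predicts (0.883 to 1.59), so lower expression by the SK-HEP1 cells themselves cannot be told apart from carry-over, since no level above the carried-over one was left to compare. Carry-over is therefore a candidate explanation for these decreases.

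Of the genes changed the same way in all 3 lines, 6 were higher and 6 lower, near the 4.60 and 3.74 of independent lists. With the GC and length trend removed 14 were higher and 10 lower against 1.13 and 1.56. These expected numbers take every gene as equally likely to be called, while the lines share 1 fit and its estimate of each gene's spread. The comparison therefore cannot decide on chance sharing. The pattern of 12 genes kept 9 of them among the 24 found with the trend removed. The trend had opposite signs in HepG2/C3A and the other lines, so its removal was a weak test of it as their cause. A part of the trend left in by the splines could also remain, so this count does not decide on it. Likewise 9 of the 12 were not open to carry-over in any line, C5, ID1 and ID3 being the exceptions. Such genes could still draw up to 10% of their level from carry-over. The changes of EGR1 exceeded this in each line, which argues against carry-over for that gene. Changes such as 0.073 for JUN in SNU-449 and -0.092 for MCM7 in HepG2/C3A lie within 10%, so the label cannot decide on them. Culture density or handling that differed between the arms may also shift immediate early and cell cycle genes, and 5 of the 12 (EGR1, JUN, CCNA2, MCM6 and MCM7) stand in those fixed lists. The labels record neither, so handling and ALK targeting cannot be told apart, and a response common to the lines stays a hypothesis.

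Splits of the samples into arms of 3 and 3 within a line number 10, too few for a share under 0.05. The real split called 2985 genes in HepG2/C3A against at most 52 in the other splits, 878 against 0 in SK-HEP1 and 3455 against 13 in SNU-449, and 7 lists against 5, 19 against 9 and 7 against 6, the real split being the 1 with as many in each case. Over the lines, 40 joint splits were drawn, the real one included. For the average of the lines, 2 of the 40 gave as many genes as the real 563, so chance was not excluded. The other one gave 695 and left SNU-449 at its real grouping, so it still held that line's difference between arms. For the difference between lines, 1 of the 40, the real one, gave 4573 genes and the highest other 812. No other drawn split left more than 1 line at its real grouping. The comparison thus bears on the grouping by arm. It cannot tell equal from unequal differences between the lines. For genes changed the same way, 1 of the 40, the real one, gave 12 and the others 0, but each of the others left at least 1 line with 0 calls, which fixed its result at 0, so this comparison does not bear on chance.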

How the results depend on the processing

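The trend removal, the settings on carry-over and on values that were not whole, and the list tests with library size only or with the trend removed and an estimated correlation were chosen after the data were seen, and the other settings were planned. Of 363 named results per gene and line, 361 were the same in direction and call with RLE scaling, 359 with library size only, 357 without a filter, 348 with limma-voom and 339 with the replicate block, which ended the other 24 calls, as were 343 of 354 with DESeq2. With the GC and length trend removed 263 of 362 were the same, 91 lost their call and 8 reversed. Of the values that passed, 68 of 118 in HepG2/C3A, 6 of 107 in SK-HEP1 and 65 of 127 in SNU-449 were then smaller by over 1.5 times. Leaving out 1 library ended the call of 100 of the 363 at least once. The cause of each change was not tested, except that a fit without a library has fewer samples.

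The count in SK-HEP1 was 1551 with the line alone and 1372 with DESeq2, which also gave 1078 on average and 19 the same way. Trend removal gave 1390 in HepG2/C3A, 1742 in SNU-449, 2502 differing between lines and 24 the same way, and with genes open to carry-over also left out 1442, 1763, 2384 and 20. In SK-HEP1 trend removal raised the count from 878 to 1127, and on average from 563 to 842. A log2 fold change of at least 1 left 39, 60 and 45 genes in the lines, 6 on average, 203 differing and 0 the same way. HepG2/C3A had 0 lists with an estimated correlation, 12 with fry, 4 with the replicate block and 4 with the line alone. The estimated correlation left 8 in SK-HEP1 and 2 in SNU-449. With the trend also removed it left 6 in HepG2/C3A, 11 in SK-HEP1 and 3 in SNU-449.

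With 1 library left out, HepG2/C3A had 2149 to 2925 genes, SK-HEP1 446 to 658, SNU-449 2570 to 3099, the average 362 to 631, the difference between lines 4050 to 4635 and the same way 6 to 15. SK-HEP1 gave 446 without control replicate 2, 484 without control replicate 3, and 516, 450 and 452 without ALK-targeted replicates 1, 2 and 3. Lists numbered 5 to 11 in HepG2/C3A (11 without control replicate 2), 15 to 20 in SK-HEP1 and 7 in each SNU-449 fit. The ratio of the target gene, ALK, in SK-HEP1 was 1.06 to 2.78. Without control replicate 1, 50.1% of the calls in HepG2/C3A were higher.

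Reversed log2 fold changes with the trend removed, with or without genes open to carry-over, were EPHA2 -0.031, SLC7A5 -0.0040, ACACA -0.038, WWC1 -0.042 and BCL2L1 -1.06e-04 in HepG2/C3A and CCNG1 -0.039, TGFB1 0.0027 and HYOU1 0.0067 in SNU-449. With 1 library left out, CD274 was -0.10 to 0.85 in HepG2/C3A, the lowest without ALK-targeted replicate 1, and -0.20 to 0.037 in SNU-449, with 0.037, 0.014 and 0.022 without control replicate 1, ALK-targeted replicate 2 and ALK-targeted replicate 3. In SK-HEP1, BCL2 was -0.16 to 0.082, the highest without control replicate 2, and BCL2L1 -0.0096 to 0.019, with -0.0026 with library size only, -0.0011 without control replicate 1 and -0.0096 without ALK-targeted replicate 2. Genes with few counts, such as ALK and CD274 in HepG2/C3A, are limited by depth.

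The replicate numbers did not pair the samples: correlations of same-numbered deviations across genes were 0.04, 0.24 and -0.17 in HepG2/C3A, -0.03, -0.09 and 0.06 in SK-HEP1 and -0.59, 0.41 and -0.48 in SNU-449, and not every sample correlated best with its own number. In SNU-449, control replicate 3 and ALK-targeted replicate 1 correlated at 0.74. Both had a HepG2/C3A share under 0.1%, unlike the line's other libraries, so this grouping crossed the arms. Controls 1 and 2 correlated with ALK-targeted replicates 2 and 3 at 0.35 to 0.43. With libraries of a low share set apart, 3490 genes changed in SNU-449. The replicate block gave 2701, 725 and 3200 genes in the lines, 421 on average, 4197 differing and 8 the same way.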

Other observations

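Single members moved in lists that did not pass as a whole. Each of the lists concerned also had at least 1 member that changed the other way. In HepG2/C3A, ASNS, the asparagine synthetase gene, fell from 544 ± 11.3 to 473 ± 11.4 CPM (SD, n = 3; edgeR adjusted p = 3.16e-06). In SK-HEP1, ANKRD1, a YAP/TEAD target, rose from 187 ± 4.99 to 231 ± 3.0 CPM (SD, n = 3; edgeR adjusted p = 8.41e-07), and GDF15, a stress-induced cytokine gene, from 106 ± 1.84 to 119 ± 2.30 CPM (SD, n = 3; edgeR adjusted p = 1.42e-04). In SNU-449, OAS3, an interferon-stimulated gene, fell from 126 ± 1.29 to 104 ± 2.68 CPM (SD, n = 3; edgeR adjusted p = 4.20e-07), with a log2 fold change of -0.27, or -0.14 with the GC and length trend removed, and STC2, which encodes the secreted glycoprotein stanniocalcin, rose from 191 ± 0.917 to 222 ± 3.52 CPM (SD, n = 3; edgeR adjusted p = 4.65e-06).

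With the GC and length trend removed, 24 genes changed the same way in all 3 lines. ATP9A, CTSB, EGR1, EREG, JUN, JUND, KLF6, MAP1B, MYADM, MYH9, SCARB2, TAGLN, TUBA1A and TUBB3 were higher, and ATXN10, C5, EPS8L2, ID1, LSM6, MCM2, MCM4, MCM6, SLC3A2 and TK1 were lower. This setting was chosen after the data were seen.

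KRT17, a keratin gene, had 508 counts in SK-HEP1 control replicate 2 and 502 in SNU-449 ALK-targeted replicate 1, and at most 18 in each of the other 16 libraries. TRIM29 had 36 and 45 counts in the same libraries and at most 11 in the other 16. Both genes were chosen after their values were seen.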
